A study of Mus musculus with 3 samples.

How the data were processed

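Single-cell RNA was measured in nasal mucosa of C57BL/6 mice from 3 groups. Per the series' design text, control mice received PBS in the nose, and the second group received 20 µg papain, a plant cysteine protease used to raise allergic inflammation. The third group received papain in the nose and lonidamine, an inhibitor of hexokinase and of lactate and pyruvate transport, at 10 mg/kg by gavage. Per the labels' protocols, the tissue of all mice of a group was pooled before processing, so each group is 1 library and no spread between animals or preparations can be measured. The number of mice per pool is not given in the sources used here. The library of the papain group has the library name Fibroblast in its labels, while its title and treatment label mark it as the model. It held all tissue classes and was used under its treatment label.

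Per the labels' protocols, the mucosa was cut up, digested with collagenase I, collagenase II and Dispase, strained, and captured with the 10x Genomics Chromium 3′ chemistry. The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, not normalized, per the file headers. Cell Ranger made them: the submitters' processing notes give version 2.1.1 and genome build GRCm39, while the file headers give version 7.1.0, and both are stated here because they differ. The barcodes are those kept by the cell calling of that pipeline; whether the authors removed further cells or doublets before deposit is not given in the sources used here. Seurat is named in the labels for the authors' own analysis, and no cell annotation of theirs was used here. Gene symbols and Ensembl identifiers were taken from the deposited feature lists. The annotation at hand was of an older mouse build, so no coordinates are given.

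The 3 matrices held 55357 genes and 9740 (PBS), 11071 (papain) and 12598 (papain with lonidamine) barcodes. Barcodes with at least 500 UMIs, at least 200 detected genes and at most 20% mitochondrial UMIs were kept, which left 9515, 10712 and 12149. Doublets were called in each library with Scrublet as provided in scanpy 1.11.5. It marked 179 (1.88%), 212 (1.98%) and 283 (2.33%) cells, which were removed. The 9336, 10500 and 11866 remaining cells carried 79338385, 82653086 and 84742740 UMIs. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes and 40 principal components were taken. A shared-neighbour graph of 20 neighbours was clustered with leidenalg 0.10.2 at resolution 1 and seed 0, all libraries together and without batch correction.

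The 43 clusters were named from 41 fixed marker sets. A marker counted when at least 10% of the cluster's cells detected it and its level was at least 3-fold that of the other cells, and a name needed at least 3 markers. A cluster also stayed unnamed when its median UMI number was below 1/3 of its libraries' and none of the markers was among its 10 leading genes. Names therefore mean that a cluster is like the type named. They gave 27 classes and left 4 clusters unnamed. Fibroblast-like cells, for example, were named from Col1a1, Col1a2, Col3a1, Dcn, Lum, Pdgfra, Dpt and Fbln1, macrophage-like cells from C1qa, C1qb, C1qc, Adgre1, Mrc1, Csf1r and Cd68, and basal epithelial-like cells from Krt5, Krt14, Krt15, Trp63, Dlk2 and Aqp3. Where such a marker is given below as a value within its class, it is not independent of the naming.

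Shares of cells are given with exact binomial (Clopper-Pearson) 95% intervals. For the 15 classes with at least 100 cells in every library, raw counts were summed per library and class and divided by the total to give CPM, the usual scaling of a count to library size. Log2 ratios were formed with 0.5 counts added to each sum. Their 95% intervals come from the conditional binomial distribution of 2 Poisson counts. All intervals, and the floors of 3 counts used where a count was 0, cover counting error only. With 1 library per group no test between groups was made, no p-value is given, and no difference reported here has a replicate check.

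Gene lists, markers, filters and the rule for named genes were fixed before the data were examined. The 30 lists were type 2 cytokines and receptors, eosinophil recruitment and granule, alternatively activated macrophage, pro-inflammatory NF-kB, interferon stimulated, collagens and structural matrix, basement membrane, matrix turnover, TGF-beta response and myofibroblast, glycolysis, lonidamine targets, hypoxia, nuclear genes of oxidative phosphorylation, mitochondrially encoded, tricarboxylic acid cycle, mucin and goblet, epithelial junction, olfactory signalling, MHC class II presentation, immunoglobulin constant, cell cycle, dissociation response, unfolded protein response, vascular activation, p53 and apoptosis, antioxidant response, complement, haemoglobin, neutrophil granule and ribosomal protein. The symbols Tcrg-C1, Cd163l1, Ero1l, Atp5f1a, Atp5f1b and Atp5pf were not among the deposited symbols. A list's members with at least 10 CPM in one of the libraries compared were measured, and their median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is not a test. Which class is shown for each list, and the closer look at interferon-stimulated genes, were chosen after the values were seen.

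Named genes had at least 100 CPM in one library and at least 100 UMIs over both, leaving out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes. Of these, the 8 highest and 8 lowest ratios per class were taken, with the same sign and at least 1.5-fold size in female and in male cells; the condition was dropped where either had fewer than 50 cells of the class. Fibroblast-like, macrophage-like and basal epithelial-like cells, the largest epithelial class, are reported in full and the other classes with 3 genes each way. Up to 4 members of each list with the largest ratios, the lonidamine target genes and the type 2 cytokine genes were added whatever their value. Some genes that these rules name are not reported here. Cells with Xist and no transcript of 4 Y-linked genes (Ddx3y, Uty, Kdm5d, Eif2s3y) were taken as female and the converse as male. Since they come from different animals of one pool, each value was computed again in both. Medians of a list by sex in the figure and in medians over classes keep the members measured over all cells, while the alternatives choose them anew in each sex.

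RNA released from broken cells gives low counts in all droplets. For a gene that another class makes, its level is therefore given as a percent of the level in the class where it was highest. To ask how far lonidamine undid the ratios seen under papain without using the same papain cells for both steps, the papain cells were split at random into 2 parts. One part was compared with PBS and the other with lonidamine, and the same was done with groups drawn from the papain cells alone. Gene ratios, list medians and second steps were also taken after thinning each cell to 1000 UMIs. This left out 375, 626 and 743 cells of the PBS, papain and lonidamine libraries. Shares of cells with a cytokine UMI are given without thinning, so differences in depth bear on them.

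The calculations were tested on simulated data drawn from the real genes and depths, with 100 genes changed 2-fold and 100 changed 4-fold. Class sums were drawn as Poisson counts, the model behind the intervals, so coverage near 95% checks the calculation only. Spread between cells, and genes that move together, were not simulated, so the intervals and percentiles may be too narrow for the real data. In the papain against PBS comparison of fibroblast-like cells (9917 genes measured), the interval covered the true ratio for 95% of the genes changed 2-fold and 99% of those changed 4-fold. Of unchanged genes, 95.7% were covered. For lonidamine against papain in the same class (9818 genes), the first 2 figures were both 98% and the last 95.4%. In basal epithelial-like cells they were 95%, 95% and 95.6% for papain against PBS (8756 genes), and 96%, 90% and 95.3% for lonidamine against papain (8735 genes). Lists without a change lay outside the 2.5 to 97.5 percentile range in 3.5%, 6%, 3.5% and 3.5% of draws of those 4 simulations. A simulated reversal of 50% was recovered as 42.5% and 43.8% in the 2 fibroblast-like simulations, so it was understated there. The basal epithelial-like simulations gave 49.7% and 49.8%. Other classes were not simulated, so reversal may be understated in them, and the cause was not tested.

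Values were recomputed under those of 17 alternatives fixed beforehand that apply to their kind. They changed the cell filter (none, or at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs), doublet removal, resolution (0.5 and 2), joint clustering, sex of the cells, minimum CPM (none or 50), the added count (5), the scaling, the weight of cells, the denominator of shares, the depth per cell and the split of the papain cells. Single clusters of the basal epithelial-like, pericyte-like and sustentacular-like classes were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.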

Results

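Nasal mucosa of C57BL/6 mice was profiled by single-cell RNA sequencing in 3 groups of 1 pooled library each. The PBS library held 9336 cells after filtering, the papain library 10500 and the library of papain with lonidamine, called the lonidamine library here, 11866. Deposited totals were 82399462, 86197965 and 89164040 UMIs, and the median kept cell carried 7321, 6545 and 5820 UMIs from 2870, 2602 and 2454.5 genes. Mitochondrial UMIs made up a median of 2.38%, 3.80% and 3.42% per cell. Nuclear 18S ribosomal RNA took 0.878%, 3.66% and 3.52% of all UMIs, a technical or biological difference between the PBS library and the others that accompanies every value below. Although the series' design text gives equal numbers of males and females in each group, the female share of cells that could be assigned was 56.8% [55.6, 58.0], 73.1% [72.1, 74.1] and 83.1% [82.3, 83.8] in the order PBS, papain, lonidamine. All square brackets give 95% intervals that cover counting error only. Because each group is 1 library, none of the differences has a replicate check, and higher or lower describes these libraries.

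The papain library, which models eosinophilic chronic rhinosinusitis, was compared with the PBS library first. Stromal cells and type 2 innate lymphocytes took larger shares in it, and olfactory neurons and monocytes smaller ones. Fibroblast-like cells were 1.46% of PBS cells and 4.79% of papain cells, 3.29-fold more, and group 2 innate lymphoid (ILC2)-like cells, a source of Il5 and Il13, were 0.193% and 0.657%, 3.41-fold more. Neutrophil-like cells were 2.63% and 6.48%, 2.46-fold more (log2 ratio 1.52 in female and 0.26 in male cells). Mature olfactory neuron-like cells, the odorant-sensing cells of the epithelium, were 27.4% and 11.3%, 2.43-fold fewer, and monocyte-like cells 4.18% and 0.752%, 5.55-fold fewer. Among immune cells alone ILC2-like cells were 3.26-fold and neutrophil-like cells 2.35-fold more frequent and monocyte-like cells 5.81-fold less frequent. Among non-immune cells fibroblast-like cells were 3.33-fold more and mature neurons 2.40-fold less frequent.

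Olfactory ensheathing-like cells were 0.428% and 1.83%, 4.27-fold more, and most other classes differed less. Shares in PBS and papain were 10.5% and 16.4% for basal epithelial-like, 4.25% and 7.47% for sustentacular-like, 1.29% and 3.02% for secretory-like, 2.15% and 3.61% for endothelial-like and 2.45% and 3.83% for pericyte-like cells. Macrophage-like cells made up 3.88% and 4.23%, T cell-like 2.39% and 3.20% (lower in male cells, -0.82), gamma delta T cell-like 3.48% and 2.08%, immature olfactory neuron-like 14.2% and 10.3% and ionocyte-like cells 5.85% and 3.51%. Immune cells together were 21.0% and 22.0%, but 17.1% and 20.4% of female and 22.3% and 13.8% of male cells. No cluster was named from the eosinophil markers. Siglecf, one of them, was among the 10 leading genes of the neutrophil-like cluster and had 212, 458 and 353 UMIs in the PBS, papain and lonidamine libraries. Epx, the eosinophil peroxidase, had 1, 2 and 1 UMIs, Prg2 24, 33 and 29, and the eotaxin receptor Ccr3 5, 14 and 24. The unnamed clusters held 4.11%, 6.92% and 6.85% of cells. The largest of them, led by Alox12e, Sprr2a3 and Reg3g, held 0.407% of PBS, 4.60% of papain and 4.24% of lonidamine cells. One led by Bpifb6, Ptgds and Ces1a held 1.96%, 1.14% and 1.39%, one led by Scgb1b27, Scgb2b27 and Car6 held 1.53%, 0.476% and 0.346%, and one led by Klk1, Fxyd2 and F5 held 0.214%, 0.705% and 0.876%.

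**Figure D1:**
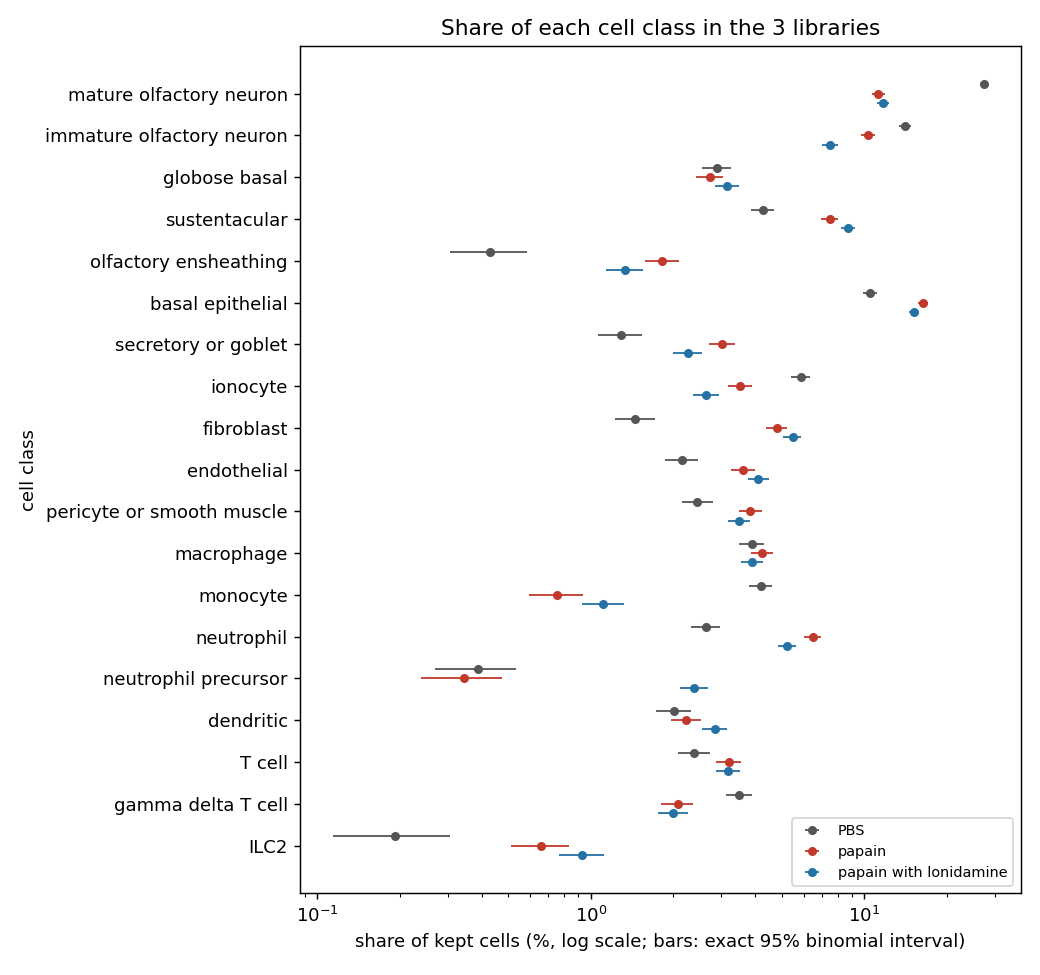
Share of kept cells in each of 19 classes, in percent on a log axis, for the PBS, papain and lonidamine libraries; points are 1 pooled library each and bars are exact 95% binomial intervals, which cover counting error only. Fibroblast-like cells go from 1.46% in PBS to 4.79% in papain and 5.47% in lonidamine, mature olfactory neuron-like cells from 27.4% to 11.3% and 11.8%, and neutrophil precursor-like cells from 0.386% and 0.343% to 2.39%.

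Il13 and Il5 were higher under papain. Il13 (ENSMUSG00000020383) had 30 UMIs in the PBS and 479 in the papain library (log2 ratio 3.92), and Il5 (ENSMUSG00000036117), the eosinophil growth factor, 57 and 425 (2.83). The alarmin Il33 (ENSMUSG00000024810) stood at 12.2 and 67.1 CPM (2.46), its receptor Il1rl1 at a ratio of 3.18, Tslp at 1.42 and Il4 at 0.57, while Il25, made by tuft cells, was lower (-1.08) and Il9 was not detected in either library. Of the 8 measured members of the type 2 list 5 were at least 2-fold higher and 1 lower over all cells (median 1.35, percentile 100 of matched random lists). In T cell-like cells the list median was 1.51, with 3 of 6 members at least 2-fold higher. Il13 was detected in 6 of 18 ILC2-like cells in PBS (33.3%) and 38 of 69 in papain (55.1%), and Il5 in 5 of 18 (27.8%) and 46 of 69 (66.7%). Among T cell-like cells 0 of 223 and 9 of 336 (2.68%) had an Il13 UMI. Background was low: 0 of 2557 mature olfactory neuron-like cells in PBS, which allows up to 0.117%, and 0 of 1183 in papain had one, at median depths of 7151 and 6694 UMIs against 3644 and 4654 in ILC2-like and 3106 and 3167.5 in T cell-like cells.

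Chil4 and Muc5ac were among the genes with the highest ratios over all cells. Chil4 (ENSMUSG00000063779), a chitinase-like secreted protein, stood at 5352 CPM over all papain cells and 26.8 in PBS, 200-fold higher, and Muc5ac (ENSMUSG00000037974), the main inducible airway mucin, at 149 and 1.34 CPM (6.79). Sprr2a3 (4.93), the interferon-inducible Ifi202b (4.41), the neutrophil chemokine Cxcl5 (122 and 5.82 CPM, 4.39), the lipoxygenase Alox15 (4.03), P-selectin Selp (3.13) and the antibacterial lectin Reg3g (7260 and 848 CPM, 3.10) were the next highest. Lowest were the odorant carriers Obp2b (-6.79) and Lcn3 (-6.13), then Rnase1 (-3.66), Pcdh10 (-3.37), S100a5 (1472 and 12035 CPM, -3.03), Cox8b (-2.77), Stmn4 (-2.60) and Ptgds (-2.47). S100a5, Pcdh10 and Stmn4 were highest in olfactory neurons, whose share was smaller. In secretory-like cells Muc5ac was 40.9-fold higher (1276 and 31.0 CPM), Chil4 stood at a ratio of 5.17 and Msln at 3.62. The mucin and goblet list had 9 of 10 members at least 2-fold higher there (median 1.87, percentile 100), among them Fcgbp (3.41), Itln1 (3.07) and Agr2 (2.04). Muc5ac and Agr2 were also markers of that class. The unfolded protein response list had a median of 0.42 in these cells, with 1 of 11 members at least 2-fold higher and 1 lower. Cox8b (-3.44) and Ppargc1a (-2.72), genes of oxidative metabolism, were lower in secretory-like cells. The mucin and goblet median was above 0 in 15 of 15 classes. Outside secretory-like cells, whose share was larger under papain, free RNA can give such medians and was not separated.

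Mmp12 and Cytl1 led the higher genes of fibroblast-like cells. The macrophage elastase Mmp12 had 517 UMIs (168 CPM) in papain and 0 in PBS, which allows up to 2.75 CPM there. Cytl1 (381 and 0.918 CPM, 8.11 [6.22, 14.00]) and the cartilage collagen Col2a1 (266 and 0.918 CPM, 7.59 [5.70, 13.48]) rested on 1 UMI each in PBS. Col2a1 was also in the marker set of chondrocytes, and such cells were not separated from the class. Whether the mix of cells sets the Cytl1 and Col2a1 ratios was not tested. Complement C3 (495 CPM in papain, 5.43), the acute-phase gene Saa3 (4.29), Cxcl5 (1697 and 102 CPM, 4.05) and Chil1 (774 and 56.0 CPM, 3.78) followed, and Chil4 stood at 6.80 but at 1.21% of its level in secretory-like cells. Saa3 was 8.29 in female and -3.59 in male cells. Lower were the sterol enzyme Fdps (-3.37), Myoc (18.2 and 183 CPM, -3.32), S100a5 (-3.23), Gm13889 (-2.94), the mitochondrial Chchd10 (-2.93), the collagenase Mmp13 (152 and 1080 CPM, -2.83), Gm14743 (-2.73) and Il1b (-2.61). Mmp13 was 6.19 in male cells and 3.04 at resolution 2, and Il1b, at 0.299% of its neutrophil level, was 1.70 in female cells. The condition on both sexes was not applied because PBS held fewer than 50 male fibroblast-like cells.

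Structural matrix genes of fibroblast-like cells showed no common direction. Col1a1 (ENSMUSG00000001506), also a marker of the class, stood at 3501 CPM in papain and 6686 in PBS (-0.93), Col1a2 at 4030 and 6507 (-0.69), Sparc at 4013 and 6125 (-0.61) and Col3a1 at 2036 and 2086. The collagen and structural matrix list had a median of 0.18 (percentile 96.0), with 2 of 22 members at least 2-fold higher and 1 lower. The matrix turnover list had 6 of 19 higher and 1 lower (0.43), the TGF-beta and myofibroblast list 2 of 17 each way (0.62), the complement list 3 of 8 higher (0.95) and the NF-kB list 9 of 17 higher and 4 lower (1.01, but -0.19 in male cells). The glycolysis list had a median of -0.62, with 1 of 15 each way. In pericyte-like cells 15 of 20 collagen and matrix genes were at least 2-fold higher (1.44, percentile 100), along with the fibroblast-rich Inmt (3.89) and Serpinf1 (3.38). Different clusters held most pericyte-like cells in the libraries, one led by Pln and Mustn1 in PBS and one led by Myh11 and Mylk in the others. Within these clusters, taken singly after the values were seen, the medians were 0.29 and 0.84.

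Macrophage-like cells carried genes of alternative activation. Retnla (ENSMUSG00000061100), induced by Il4 and Il13, had 773 UMIs in papain and 2 in PBS (380 and 0.687 CPM, 8.79 [7.25, 12.16]). The eotaxin Ccl24 (ENSMUSG00000004814; 233 and 18.9 CPM, 3.62), Il10 (278 and 22.7 CPM, 3.61), Areg (3.43) and Nrg1 (3.24) were also higher. Chil4 (7.71), Reg3g (4.86) and Wfdc18 (3.26) were high too but stood at 1.14%, 1.14% and 0.728% of their level in epithelial classes. Gpnmb (86.5 and 1033 CPM, -3.57), Ptgds (-3.55), the lipid carrier Fabp4 (-2.65) and the lysosomal protease Ctsd (1281 and 6389 CPM, -2.32) were lower, as were Gpx6 (-2.40) and the neuronal S100a5 (-2.98), Stoml3 (-2.30) and Pcp4l1 (-2.25). Of the alternatively activated macrophage list 9 of 10 members were at least 2-fold higher (2.60), and of the eosinophil recruitment list 5 of 6 (3.39), among them Ccl8 (679 and 75.5 CPM, 3.17). MHC class II genes were 5 of 9 higher (1.03). Glycolysis genes were 7 of 15 at least 2-fold lower (-0.99, percentile 0), while the hypoxia list stood at 0.12, with Ndrg1 at 2.59. All-gene medians in this comparison were -0.19 in secretory-like, -0.13 in basal epithelial-like and endothelial-like, -0.10 in macrophage-like and 0.13 in mature neuron-like cells, and list medians can be read against these.

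In basal epithelial-like cells the stress keratin Krt16 and 4 of 10 junction genes were among the higher ones. Chil4 (3844 and 65.4 CPM, 5.88), Krt16 (206 and 8.17 CPM, 4.64), Ifi202b (508 and 36.5 CPM, 3.80), Ltf (3.20), Wfdc18 (3.06), Aldh1a1 (2.83), Itpkc (2.83) and C3 (277 and 40.6 CPM, 2.77) were highest. Ltf and Wfdc18 were at 1.81% and 0.667% of their serous gland level, and stood at -0.59 and -1.15 with each library clustered alone. Gpnmb (-4.02), Cox8b (-4.01), S100a5 (-3.27), the quinone reductase Nqo1 (45.0 and 294 CPM, -2.71), the sterol enzymes Fdps (-2.31) and Msmo1 (-2.24), Fabp5 (-2.23) and Chchd10 (-2.13) were lowest. Of the epithelial junction list 4 of 10 members were at least 2-fold higher (0.80, percentile 100): Cldn4 (751 and 144 CPM, 2.39), Ocln (1.91), Cdh1 (1.26) and Dsp (1.04). Nuclear genes of oxidative phosphorylation had a median of -0.53 and the tricarboxylic acid cycle of -0.68, with 1 of 20 and 3 of 14 at least 2-fold lower; both medians were below 0 in 15 of 15 classes. The ribosomal protein list, a technical check, was also below 0 in 15 of 15, with a median over classes of -0.38 beside -0.32 and -0.39 for these 2 and -0.47 for glycolysis. The basement membrane list stood at 0.46. The cell cycle list had 6 of 10 members at least 2-fold higher (1.10), but -0.24 within the cluster led by Ifi202b and Krt15. That cluster held 41.1% of the papain and 20.6% of the PBS cells of the class, and one led by Nrcam and Abca4 held 16.4% and 49.9%.

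Vessels, neutrophils and neurons also differed. Endothelial-like cells had higher Csf3 (414 and 29.5 CPM, 3.80), the granulocyte growth factor, and lower Gdf15 (3.75 and 658 CPM, -7.40), Olfm2 (-6.89) and Ptgds (-6.18). The NF-kB list there had 11 of 16 members at least 2-fold higher and 1 lower (1.53), the interferon list 8 of 15 higher (1.18), among them Cxcl10 (1328 and 136 CPM, 3.29), and the vascular activation list 5 of 11 higher and 2 lower (0.60). The leukocyte adhesion molecules Selp (2835 and 411 CPM, 2.79) and Sele (780 and 279 CPM, 1.48) and the chemokine receptor Ackr1 (1.68) were higher and Apln was lower (-2.44); Selp and Sele were among the leading genes of the cluster. Neutrophil-like cells had higher Saa3 (274 and 5.16 CPM, 5.51) and Tnf (2021 and 296 CPM, 2.77), an NF-kB list median of 0.70 and a ribosomal protein median of -0.84. Apoe (-3.05) and Cyp1a2 (-2.96, but 0.23 in female cells) in these cells were at 2.59% and 3.17% of their highest class. Mature olfactory neuron-like cells had 0 UMIs of Lcn3 and Lcn4 in papain and 467 and 400 CPM in PBS, Obp2b stood at 0.250 and 450 CPM, and the receptor Olfr1408 was higher (5.05). The olfactory signalling list in them stood at 0.32, with 1 of 12 members at least 2-fold higher, and the dissociation response list at -0.32. In immature neuron-like cells Olfr1046 was higher (4.81) and Bglap3 (-4.60), H4c9 (-1.96) and Stmn4 (-1.87) lower. The cells behind the values of Olfr1408 and Olfr1046 were not counted, and a few may set them.

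Sustentacular-like cells, the supporting cells of the olfactory epithelium, had Chil4 at 10200 CPM against 1 UMI in PBS (15.24 [13.35, 21.13]), with higher Bpifb3 (552 and 11.2 CPM, 5.61) and Ltf (4.11, at 6.86% of its serous gland level) and lower Calb1 (-3.49, but 0.98 at resolution 2), Cox8b (-3.22) and Adora2b (-3.11). Bpifb3 and Ltf were at -1.11 and -0.68 within a smaller cluster led by Kcnk2 and Muc2. Their MHC class II list stood at 1.34, from which free RNA of other classes was not separated. A cluster led by Chil6 and Cyp1a1 held 60.2%, 36.9% and 39.7% of these cells in the PBS, papain and lonidamine libraries, and one led by Muc2 and Sec14l3 held 10.3%, 43.6% and 47.7%. Ionocyte-like cells had higher Pigr (3.20) and Ltf (3.21), at 8.04% and 0.937% of their highest class, and lower Rnase1 (188 and 1530.2 CPM, -3.02), S100a5 (-3.43) and Spp1 (-2.87). Globose basal-like cells had higher Wfdc18 (5.81) and Gm14744 (4.85) at 1.29% and 0.378% of their serous gland level, and lower Cd74 (-1.67, but 0.88 in female cells), Fdps (-1.42) and S100a5 (-1.35). T cell-like cells had lower Xcl1 (14.0 and 170 CPM, -3.56), Ly6d (-3.25) and Aldh2 (-3.21), the last pair turning to 2.72 and 1.08 with libraries clustered alone, and higher Tff1 (309 and 0 UMIs) and Nrgn (5.29 [3.95, 7.80]). Gamma delta T cell-like cells had a lower activation marker Cd69 (114 and 515 CPM, -2.17), with Reg3g (4.26) and Wfdc18 (3.85) at 0.699% and 0.998% of their highest class. Dendritic-like cells had higher Olfr77 (139 and 1 UMIs, from a number of cells not counted) and Wfdc18 (4.35). Lower there were Pcp4l1 (-3.74) and Stoml3 (-2.22) at 3.62% and 2.87% of their neuronal level. Chil4 was among the 3 highest genes of every one of these classes at 0.314% to 1.59% of its secretory level, the sustentacular-like class apart, and S100a5, Gm14743 and Mup4 were low in pericyte-like cells at 0.226% to 1.62% of their highest class.

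Other lists are given over all cells, papain against PBS. Lonidamine targets had a median of -0.36 (percentile 5.37), with Hk2 (ENSMUSG00000000628), the inducible hexokinase, at 96.9 and 46.1 CPM (1.07). Antioxidant genes stood at 0.12 (Hmox1 1.16), p53 and apoptosis genes at -0.03 (Pmaip1 1.87), mitochondrially encoded genes at 0.05, immunoglobulin constant genes at 0.38, haemoglobin at 0.39 and neutrophil granule genes at 0.14. The interferon list stood at 0.59 over all cells (-0.09 among genes of at least 50 CPM) and 0.80 in macrophage-like (-0.05 at resolution 0.5), 0.03 in fibroblast-like (1.52 in male cells) and 0.04 in basal epithelial-like cells.

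**Figure D2:**
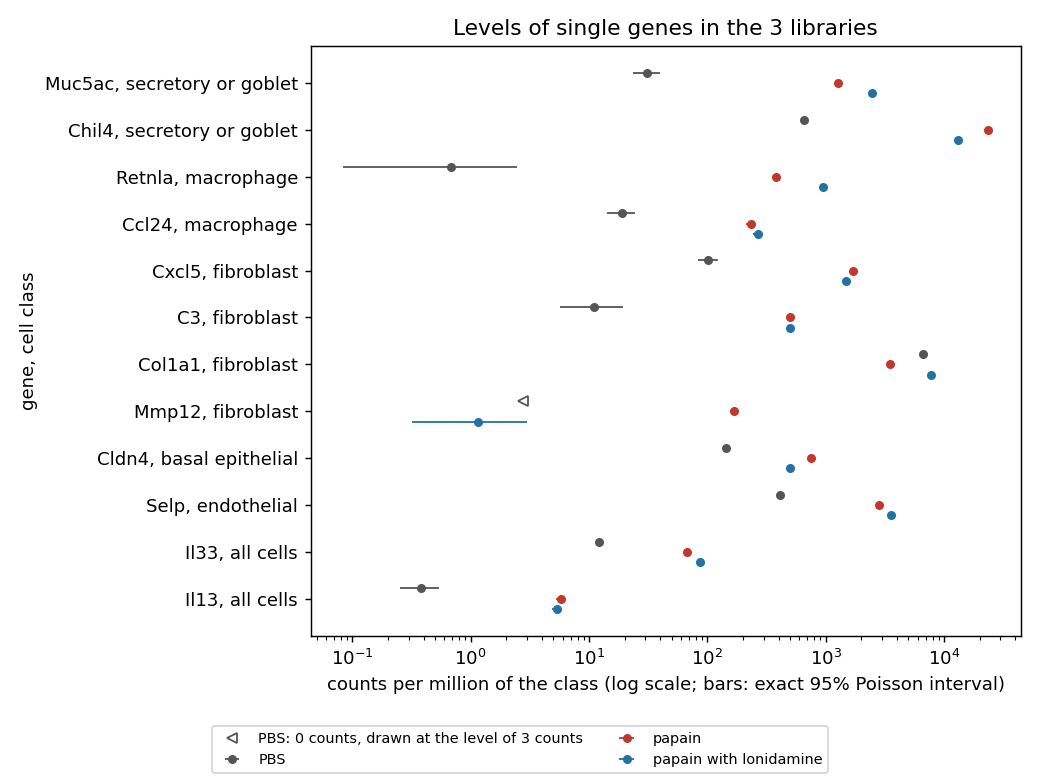
CPM on a log axis of 12 genes in the class named beside each, in the PBS, papain and lonidamine libraries; points are 1 pooled library with exact 95% Poisson intervals, and an open triangle marks 0 counts at the level of 3 counts. Muc5ac in secretory-like cells goes from 31.0 to 1276 and 2473 CPM and Retnla in macrophage-like cells from 0.687 to 380 and 941, while Mmp12 in fibroblast-like cells is 168 CPM in papain and 1.16 in lonidamine.

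The comparison of lonidamine with papain alone asks whether the drug eased inflammation and tissue remodelling in this model, the aim named in the title of the series. Most classes had similar pooled shares, and over all cells Il13 and Il5 were close to their papain levels. The largest ratios of shares were in squamous epithelial-like and in neutrophil precursor-like cells. Squamous epithelial-like cells, led by Krt1 and Krtdap, were 0.162% of papain and 1.31% of lonidamine cells, 8.12-fold more. In the lonidamine library 150 of them were female and 0 male, and with each library clustered alone the log2 ratio was -1.67 [-1.95, -1.40]. Neutrophil precursor-like cells, named from granule genes such as Elane and Mpo, were 0.343% and 2.39%, 6.98-fold more, and 6.35-fold more among immune cells. ILC2-like cells were 0.657% and 0.927% (log2 ratio 0.50), fibroblast-like cells 4.79% and 5.47% (0.19), neutrophil-like cells 6.48% and 5.23% (-0.31) and mature olfactory neuron-like cells 11.3% and 11.8% (0.06). These values differed by sex: neutrophil-like cells stood at -0.98 in female and 0.70 in male cells and mature neurons at -0.72 and 1.49. Of the 2 clusters of mature neurons, the larger held 10.2% of papain and 9.48% of lonidamine cells, and one with a median depth 0.242 of its libraries', led by Obp2a and Hbb-bs, 1.02% and 2.28%. In male cells fibroblast-like cells were at -0.24 and ILC2-like cells at -0.17, and fibroblast-like cells at 0.0028 with each library clustered alone. Macrophage-like cells were 4.23% and 3.89%, basal epithelial-like 16.4% and 15.2% (higher in female cells, 0.24), secretory-like 3.02% and 2.27% (3.31% and 3.16% of female, 2.99% and 0.317% of male cells) and monocyte-like cells 0.752% and 1.11% (lower in male cells, -0.49).

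Among lonidamine's target genes, the monocarboxylate transporter Slc16a3 had the largest ratio over all cells (0.73), then the chloride channel Cftr (-0.31), Slc16a1 (0.28), Slc16a7 (0.21) and Hk2 (-0.17), and the list median was 0.04 (percentile 73.0). Il13 had 479 and 452 UMIs in papain and lonidamine (-0.12), Il5 425 and 341 (-0.35), Il4 39 and 56 (0.48) and Il9 0 and 2. Il33 stood at 67.1 and 86.5 CPM (0.37), Il1rl1 at 0.37, Tslp at 0.0036 and Il25 at -0.44. None of 7 measured type 2 list members differed 2-fold (median 0.0037, percentile 34.6). Il13 was detected in 38 of 69 and 67 of 110 ILC2-like cells (55.1% and 60.9%) and Il5 in 46 of 69 and 58 of 110 (66.7% and 52.7%), at median depths of 4654 and 3535 UMIs. In T cell-like cells 9 of 336 and 19 of 377 (2.68% and 5.04%) had an Il13 UMI, and Il13 stood at 34.3 and 101 CPM (1.55). Il4 was detected in 1 and 12 of these cells (0.298% [0.0075, 1.65] and 3.18% [1.66, 5.49]) and Il5 in 4 and 8 (1.19% and 2.12%). In ILC2-like cells Il4 was detected in 13 of 69 and 15 of 110 (18.8% and 13.6%). The list median in T cell-like cells was 0.77, but -0.03 with the mean of per-cell CPM. Of the mature olfactory neuron-like cells of the lonidamine library, 1 of 1395 had an Il13 UMI.

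Medians of the interferon-stimulated list lay below 0 for lonidamine against papain in all compared classes, though not for each gene or setting. Over all cells Isg15, a ubiquitin-like product of interferon signalling, stood at 23.4 CPM against 62.3 (-1.41) and Ifit3 at -1.07, and the interferon list had a median of -0.50 (percentile 0), with 2 of 12 members at least 2-fold lower and none higher. The median was below 0 in 15 of 15 classes, in both sexes in 13, from -1.39 in sustentacular-like to -0.09, and it lay under the 2.5 percentile in 10. Fibroblast-like cells had 4 of 12 members at least 2-fold lower (-0.80), pericyte-like cells 6 of 13 (-0.75, but 0.01 in female cells) and secretory-like cells 4 of 10 (-0.76), with Isg15 (69.4 and 191 CPM, -1.46) and Cxcl10 (242 and 621 CPM, -1.36) lower in pericyte-like and Isg15 (219 and 512 CPM, -1.22) in endothelial-like cells. Endothelial-like, macrophage-like and basal epithelial-like cells had medians of -0.25, -0.31 and -0.53. The basal epithelial-like value was 0.10 among genes of at least 50 CPM and 0.13 within the cluster led by Ifi202b and Krt15. Against PBS, the lonidamine library's median was -0.39 over all cells and -1.15 in fibroblast-like cells.

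**Figure D3:**
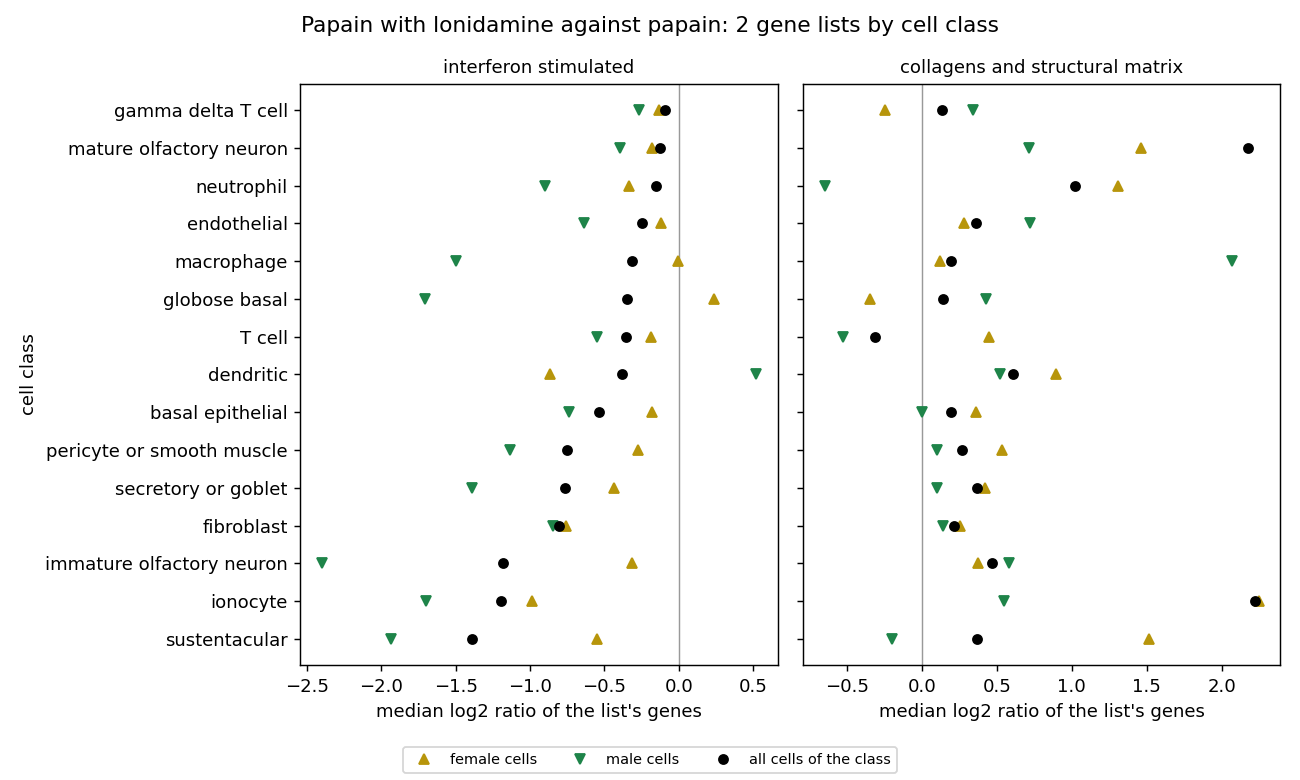
Median log2 ratio, lonidamine against papain, of the interferon-stimulated list and of the collagen and structural matrix list in each compared class; black points are all cells and triangles are female and male cells of the same pools, with no replicate libraries. Interferon medians lie below 0 in 15 of 15 classes, from -1.39 to -0.09, and collagen medians above 0 in 14 of 15, in both sexes in 13 and 9 of them. Free RNA of fibroblast-like cells was not separated from the collagen medians of other classes.

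Col1a1 and Col1a2 were higher, not lower, over all fibroblast-like cells of the lonidamine library, though Col1a1 was not higher in male cells. Col1a1 stood at 7799 and 3501 CPM in lonidamine and papain (1.16 [1.12, 1.19]; 1.39 in female and -0.15 in male cells) and Col1a2 at 8418 and 4030 (1.06), with Sparc at 5726 and 4013 (0.51) and Col3a1 at 2311 and 2036. The collagen list median was 0.22 (percentile 100), with 2 of 21 members at least 2-fold higher, but -0.05 with each library clustered alone. In pericyte-like cells it was 0.26. The matrix turnover list had 1 of 20 higher and 2 lower (0.18, but -0.08 with thinned cells and -0.05 with libraries clustered alone), the TGF-beta list 1 of 17 higher (0.0019), namely Cthrc1 (45.9 CPM in lonidamine, 1.60), the NF-kB list 2 of 16 each way (-0.19, 0.05 in male cells), with Lcn2 at 51.1 and 192 CPM (-1.91), the complement list none of 8 (-0.03) and the glycolysis list none of 15 (-0.13, 0.07 with no cell filter). Mmp12 (1.16 and 168 CPM, -7.01 [-9.06, -5.81]) and Saa3 (5.23 and 188 CPM, -5.13) were the lowest genes, then Coch (-1.63, at 0.981% of ionocytes), Nr2f1 (-1.16), Sparcl1 (-1.16) and the interferon-inducible Bst2 (-1.14), Iigp1 (-0.99) and Cxcl10 (-0.93). Mmp13 (577 and 152 CPM, 1.92) and the bone sialoprotein Ibsp (603 and 225 CPM, 1.42) were higher, but stood at -3.82 and -7.14 with libraries clustered alone and at -1.57 and -2.06 at resolution 2. Ibsp was also in the marker set of the osteoblast lineage, and such cells were not separated from the class. Whether the mix of cells sets its collagen ratios was not tested. Bpifb6 (3.73) and Gpx6 (3.28) were higher as well, along with the secreted gland transcripts Mup4 (2.27), 5430402E10Rik (1.94), Obp1b (1.72) and Obp1a (1.44), at no more than 0.234% of their serous gland level.

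Macrophage-like cells kept high Retnla, at 941 CPM against 380 in papain (1.31 [1.18, 1.43]), and the alternatively activated list had 2 of 11 members at least 2-fold higher (0.20), with Folr2 (1.18), the lectin Mgl2 (0.62) and the mannose receptor Mrc1 (637 and 443 CPM, 0.52). Hspa1b (1.42), Bpifb6 (1.26), Gpx6 (1.13), and Mup4 (1.24), Coch (1.23) and Vmo1 (1.19) at 0.247% to 1.02% of their highest class, and Ear2 (133 and 62.9 CPM, 1.07) were also higher; Coch and Ear2 were lower in male cells (-0.89 and -0.51). The lowest genes, Sfn (-2.36), Krt15 (-2.25), Reg3g (-2.04), Chil4 (-2.04), Timp3 (-1.97), Epas1 (-1.83), Krt14 (-1.76) and Ly6d (-1.74), are mostly epithelial and stood at 1.14% to 3.67% of their highest class. With no cell filter Reg3g was at 1.20, Chil4 at 0.55, Ly6d at 0.66 and Krt15 at 0.09, and Krt15 was at 0.16 in female and Ly6d at 0.04 in male cells. Fewer than 50 male cells were present, so the sexes set no condition here. The eosinophil recruitment list stood at 0.28 (-0.75 in male cells), MHC class II at -0.23, hypoxia at -0.27 and glycolysis at -0.0070. In sustentacular-like cells MHC class II genes were 3 of 6 at least 2-fold lower (-1.06). Free RNA of other classes was not separated from that value.

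Basal epithelial-like cells had lower keratins Krt16 (94.4 and 206 CPM, -1.12) and Krt6a (154 and 287 CPM, -0.90), and lower Rgs5 (-0.86, at 0.872% of its pericyte level), ubiquitin Ubb (-0.79), Sftpd (-0.48) and the iron-binding Lcn2 (-0.40, but 0.22 within the cluster led by Pthlh). Tef (0.75), the glucocorticoid-induced Tsc22d3 (0.72), Bhlhe40 (634 and 418 CPM, 0.60) and Tns4 (0.59) were higher, the last 2 at -0.06 and -0.0052 within the cluster led by Nrcam, and Mup4 (2.20), Obp1b (1.71), Obp1a (1.56) and Gm14744 (1.48) at up to 0.144% of their serous gland level. The junction list stood at -0.12 (0.06 in female cells), with Cldn4 (502 and 751 CPM, -0.58) and Epcam (-0.47), oxidative phosphorylation at -0.08, the tricarboxylic acid cycle at 0.07, basement membrane at 0.07 and the cell cycle at 0.35 (0.97 in female and -0.70 in male cells, and -2.14 with libraries clustered alone). In secretory-like cells Muc5ac (2473 and 1276 CPM, 0.95) and Fcgbp (680 and 236 CPM, 1.53, but -0.17 in male cells) were higher and Bpifb1 lower (-0.90), and the mucin list median was 0.76, with 2 of 11 members at least 2-fold higher. Male cells gave -0.88 for the list, from 5 cells in the lonidamine library. Bpifb4 (-3.74), Gpx6 (-3.53) and Bpifb6 (-3.49) were lowest there, but stood at 0.12, 0.71 and 0.57 at resolution 0.5 and at 0.36, 0.52 and 0.79 with called doublets kept. They were also above 0 with no cell filter and in male cells. A cluster of 25 cells led by Fcgbp and Mrgprg, 7.89% of the secretory-like cells of papain, had no cells in the other libraries. The unfolded protein response stood at 0.09.

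Over all cells the granule genes Ngp (425 and 14.4 CPM, 4.88), Camp (512 and 18.7 CPM, 4.78), S100a8 (1460 and 284 CPM, 2.36) and S100a9 (2.19) were higher, with the neutrophil granule list at 2.19 (5 of 7 at least 2-fold higher) and haemoglobin at 3.04 (4 of 4). Then came 5430402E10Rik (0.94), Gpr155 (0.91), Ldhd (0.91) and Bpifb6 (0.81). Sprr2a3 (-1.13), Chil4 (2783 and 5352 CPM, -0.94), Cldn4 (205 and 350 CPM, -0.77) and Cxcl5 (71.9 and 122 CPM, -0.77) were lower. Immunoglobulin constant genes stood at 0.49, with Igha at 267 and 139 CPM (0.94), p53 at -0.05, antioxidant genes at -0.04 and mitochondrially encoded genes at 0.0056. Sustentacular-like cells had lower Cxcl5 (24.8 and 234 CPM, -3.24), Chil4 (3087 and 10200 CPM, -1.72) and Ifitm3 (-1.47) and higher Fmo5 (1.38, but -2.34 [-2.54, -2.15] with each library clustered alone). Cxcl5 and Ifitm3 were there at 7.53% and 4.78% of their highest class. Endothelial-like cells had a vascular activation median of 0.32 (-0.42 in male cells) and an NF-kB median of -0.22 (0.24 with thinned cells and 0.0046 with the mean of per-cell CPM), with lower Emp3 (-0.83) and Chil4 (-0.79). Pericyte-like cells had lower Rasd1 (-0.81) and higher Ltf (2.93, but -0.02 within the cluster led by Pln) at 2.04% of its serous level. Globose basal-like cells had the carbonic anhydrases Car1 (4.60) and Car2 (3.48) higher and the neuronal Stoml3 (-3.57), Omp (-3.39) and Gng13 (-3.10) lower, at 1.63% to 2.07% of their neuronal level; Car1 and Car2 stood at -5.14 and -3.63 with libraries clustered alone.

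Neurons of the lonidamine library differed in single odorant receptors: Olfr24 was higher in mature (1.75) and immature (6.17) and Olfr1046 lower in both (-3.16 and -1.63, the latter at 0.26 with called doublets kept and 0.28 with no cell filter), as were Olfr958 (-1.99) and Olfr1408 (-1.94) in mature neuron-like cells, and Ubb (-0.87) and Gm47283 (-0.86) in immature ones. The cells behind each receptor were not counted, and the intervals treat UMIs as independent, so a few cells may set these ratios. The same limit holds for Olfr981 and Olfr77 in immune classes below. The olfactory signalling list stood at 0.10 and the dissociation response at -0.05 in mature neurons. The dissociation list, a technical check, was above 0 in 11 of 15 classes and above the random range in 8, with 0.31 in basal epithelial-like and neutrophil-like and 0.32 in dendritic-like cells. Ionocyte-like cells had higher Klk1 (3.39) and lower Cd74 (-1.19) and Chil4 (-0.67, but 1.19 with libraries clustered alone), at 0.389% and 0.553% of their highest class. Gamma delta T cell-like cells had lower H2-Ab1 (-1.72), H2-Eb1 (-1.61) and Selenom (-1.32) and higher Gap43 (2.43), at 1.05% to 8.01% of their highest class. In female cells, 89.8% of those assigned in lonidamine, H2-Ab1 was at 0.18 and H2-Eb1 at 1.36 [0.17, 2.89]. T cell-like cells had lower Gzma (-2.36, but 4.12 in male cells), Chil4 (-1.13, but 0.05 with called doublets kept) and Tff1 (-1.11, but 2.28 in male cells) and 168 UMIs of Olfr981 against 0. Dendritic-like cells had lower Olfr77 (-6.77 [-12.67, -4.85]), Fstl5 (-2.40) and F3 (-2.10, but 0.77 in male cells), the last 2 at 3.26% and 3.41% of their highest class. Neutrophil-like cells had lower neuronal Tubb2b (-2.59) and Stmn2 (-2.23), at 5.42% and 5.04% of their immature neuron level, with a ribosomal protein median of -0.29 (0.09 with no cell filter) and an NF-kB median of -0.05. The other high genes of these classes were granule genes S100a8 and S100a9 at up to 0.116% (S100a9 -0.24 in male T cell-like cells), gland transcripts (Mup4, Obp1a, Obp1b, Gm14743, 5430402E10Rik) at up to 0.544% and Stoml3 in ionocyte-like cells at 0.917% of their highest class.

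Differences between the papain and PBS libraries were not undone as a whole in the lonidamine library. They may include a difference of preparation, since 18S ribosomal RNA took 0.878% of UMIs in PBS and 3.66% and 3.52% in the other libraries. Such a difference would be shared by both papain-treated libraries, would also appear as not undone, and was not separated. With separate papain cells for the 2 steps, 747 genes at least 2-fold higher in papain fibroblast-like cells (median 1.38) had a median of 0.10 [0.06, 0.15] from papain to lonidamine, against -0.0097 between groups drawn from papain alone, and 721 lower genes (-1.27) had -0.06 against -0.30. In basal epithelial-like cells 437 higher genes (1.40) had 0.01 against -0.03 and 537 lower genes (-1.23) had 0.07 against -0.59, the latter from 9 genes, and in macrophage-like cells 801 higher genes (1.48) had -0.09 against 0.08 and 864 lower genes (-1.33) had -0.06 against -0.02. Over classes and directions the medians of unchanged groups ranged from -0.59 to 0.30. They rest on smaller parts of the papain cells and on other genes, so they are only a rough measure for the second steps. The largest second step of higher genes was 0.24 [0.21, 0.28] in endothelial-like cells, against -0.04. It went further from PBS, but stood at -0.13 in male cells. Among lower genes the largest was 0.19 [0.15, 0.24] in secretory-like cells, towards PBS, against 0.06. The share of the first step that was undone ranged from -17.5% to 14.9% over classes and directions. The covariance of the steps over genes was 0.0186 in fibroblast-like, -0.0012 in basal epithelial-like and -0.0133 in macrophage-like cells, beside 0.0541, 0.00075 and 0.0146 for the unchanged groups.

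The lonidamine library was last set against the PBS library that also served papain, so genes high in both comparisons are no separate evidence. Among fibroblast-like cells Cytl1 (8.33 [6.44, 14.22]), Chil4 (7.61), Col2a1 (6.41), C3 (5.45), Cxcl5 (1487.5 and 102 CPM, 3.86), the retinoic acid hydroxylase Cyp26b1 (3.85), Chil1 (3.68) and Kcnj15 (3.25) were highest. S100a5 (-4.57), Gm13889 (-3.29), Pcp4l1 (-3.18), the sterol enzymes Sqle (-3.10), Fdps (-3.08) and Msmo1 (-2.77), Chchd10 (-2.75) and Myoc (-2.72) were lowest. As above, chondrocytes were not separated from the class, which bears on Cytl1 and Col2a1. Col1a1 was at 7799 and 6686 CPM (0.22), and the collagen list had 2 of 22 members each way (0.38). In macrophage-like cells Retnla (10.10 [8.56, 13.47]), Chil4 (5.67), Ear2 (5.21), Ccl24 (3.81), Ccl8 (3.67), Il10 (3.51), Il6 (3.49) and the T cell chemokine Ccl5 (3.30) were higher and S100a5, Stoml3 (-3.04), Gpnmb (-2.99), Fabp4 (-2.84), Pcp4l1, the matrix glycoprotein Spp1 (-2.39), Gm26532 (-2.30) and the galectin Lgals1 (-2.14) lower, with 11 of 11 alternatively activated genes at least 2-fold higher (2.83). In basal epithelial-like cells Chil4 (5.65), Ifi202b (3.47), Ltf (3.24), Wfdc18 (3.13), Aldh1a1 (2.95), Itpkc (2.94), C3 (2.92) and the phosphodiesterase Pde4b (2.39) were higher and Cox8b (-4.17), Gpnmb (-3.75), S100a5 (-3.40), Fdps (-2.91), Nqo1 (-2.76), Fabp5 (-2.46), Msmo1 (-2.46) and Abca4 (-2.12) lower. The type 2 list stood at 1.22, mucins in secretory-like cells at 2.40 and the cell cycle in basal epithelial-like cells at 1.46. All-gene medians above 0.1 were 0.12 in T cell-like, 0.22 in gamma delta T cell-like, 0.10 in globose basal-like, 0.17 in immature and 0.17 in mature neuron-like cells.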

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

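In this part the tests of the dissected area, of the cell filter, of bone marrow and of damaged cells were chosen only after the result was seen, as was reading the test of the sexes from female cells alone for the precursors.

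Share ratios of 7 classes had opposite signs in the female and the male cells of the same libraries. They were singled out because both log2 share ratios had counting intervals clear of 0 on opposite sides. The differences between sexes were not tested, since each sex is 1 pool per library. Mature olfactory neuron-like cells, lonidamine against papain, stood at -0.72 [-0.87, -0.56] in female and 1.49 [1.21, 1.77] in male cells, beside 0.06 pooled. Neutrophil-like cells in the same comparison stood at -0.98 and 0.70 (-0.31 pooled), and basal epithelial-like cells at 0.24 and -1.14 (-0.11 pooled). Globose basal-like cells gave 0.93 and -0.47 (0.21 pooled) and B cell-like cells 0.59 and -2.49 (0.39 pooled). Under papain against PBS, T cell-like cells stood at 0.90 and -0.82 (0.42 pooled) and macrophage-like cells at 0.49 and -0.61 (0.13 pooled).

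Mature olfactory neuron-like cells were fewer in the papain library (log2 share ratio -1.28). Less olfactory epithelium in the dissected tissue, lost evenly, would lower the other olfactory classes alike. The median ratio of immature neuron-like, globose basal-like, sustentacular-like and olfactory ensheathing-like cells was 0.36. This lies 1.64 above that of the mature neurons (at least 1.33 with counting error). The ratios spread widely, in that order -0.45, -0.09, 0.81 and 2.09, so their median is a poor measure of the amount of epithelium. The sustentacular-like rise lay mostly in the cluster led by Muc2 and Sec14l3 (0.439% of PBS and 3.26% of papain cells). The values of immature neuron-like and globose basal-like cells, above that of the mature neurons, argue only against an even loss as the whole cause. A different mix of female and male mice is argued against by ratios of -1.34 in male and -1.40 in female cells. Loss of damaged neurons to the cell filter is argued against by -1.25 without any filter. The filter took few barcodes, leaving 10712 of 11071 in papain and 9515 of 9740 in PBS. Neurons lost earlier, in dissociation or cell calling, are not covered, so such loss stays open. So does less olfactory epithelium as a part of the cause, since immature neurons were also fewer, and so does an uneven loss of it. An effect of papain on these neurons stays open too, as a hypothesis untested apart from the library it came in.

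Neutrophil precursor-like cells made up 0.343% of the papain and 2.39% of the lonidamine library (2.80). Bone marrow in the dissected tissue cannot be told apart from an effect of lonidamine: 7 genes of other marrow lineages had a median log2 ratio of 0.46, with the erythroid Alas2 at 2.40 (53 and 289 UMIs) and the B cell precursor genes Vpreb1 at 0.46, Vpreb3 at 0.47, Igll1 at 0.03, Rag1 at 0.11 and Dntt at 0.15. A different mix of female and male mice as the whole cause is argued against by a ratio of 3.38 [2.57, 4.32] within female cells alone (183 precursors in lonidamine and 13 in papain). Male cells held 0 and 4, and 0 among 1578 allow a share of up to 0.190%. What stays open is lonidamine, marrow in this 1 pool, or single animals.

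Nuclear 18S ribosomal RNA took 0.878% of UMIs in the PBS library and 3.66% and 3.52% in the others. A difference between library preparations requires that all cells share it, and 15 of 15 classes were at least 2-fold higher in papain, with log2 ratios from 1.57 to 3.34. Since the preparation and papain coincide, an effect of papain on all cells stays open. With the stricter cell filter the ratio was 2.065, beside 2.06. This cannot decide on more damaged cells, because the share is taken over summed UMIs, to which cells of low depth add little. Median mitochondrial UMIs per cell were 2.38% in PBS and 3.80% in papain, so damage stays open.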

How the results depend on the processing

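The alternatives that took single clusters of a class alone were chosen after the data were seen, and all others were planned. No paired analysis was possible because each group is 1 library, pooled from all its mice. A value counted as moved when it left the 95% interval of the main value, which covers counting error for genes and shares and the spread over genes for list medians and second steps. It counted as turned when its sign changed and the main interval excluded 0, or, for lists, the main percentile lay outside the central 95%. The 265 ratios of named genes gave 3180 values, of which 2170 stayed, 961 moved and 49 turned. The 53 ratios of shares gave 459 values (380, 69 and 10), the 86 list medians 1255 (1164, 65 and 26), and the 30 medians of the second step, from papain to lonidamine, 480 (277, 157 and 46). None of the 265 gene ratios turned with thinned cells, per-cell means, another scaling, 5 added counts or the stricter filter, while 13 did in male cells. With no minimum CPM and with 5 added counts 86 of 86 list medians kept their sign, and shares among immune or among non-immune cells kept it for 53 of 53. Scrublet marked 0 cells of the unfiltered lonidamine library, so none were removed there. An alternative gave no value where a class had no cells in a library or a list no measured member. The cause was not tested for any value below. Depth limits genes that rest on few counts, such as Cytl1 and Col2a1 in fibroblast-like cells with 1 UMI each in PBS. Class names below stand for cells like the type named.

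Named genes turned sign as follows, in log2 ratios with the class after the gene. With no cell filter, lonidamine against papain gave Bpifb4 0.066, Bpifb6 0.64 and Gpx6 0.43 in secretory, Chil4 0.55, Krt15 0.085, Ly6d 0.66 and Reg3g 1.20 in macrophage and Olfr1046 0.28 in immature neuron. With called doublets kept, lonidamine against papain gave Bpifb4 0.36, Bpifb6 0.79 and Gpx6 0.52 in secretory, Chil4 0.045 in T cell and Olfr1046 0.26 in immature neuron. With resolution 0.5, lonidamine against papain gave Bpifb4 0.12, Bpifb6 0.57 and Gpx6 0.71 in secretory. With resolution 2, papain against PBS gave Calb1 0.98 in sustentacular and Mmp13 3.04 in fibroblast, and lonidamine against papain gave Ibsp -2.06 and Mmp13 -1.57 in fibroblast. With each library clustered alone, papain against PBS gave Aldh2 1.08 and Ly6d 2.72 in T cell and Ltf -0.59 and Wfdc18 -1.15 in basal epithelial, and lonidamine against papain gave Car1 -5.14 and Car2 -3.63 in globose basal, Chil4 1.19 in ionocyte, Fmo5 -2.34 in sustentacular and Ibsp -7.14 and Mmp13 -3.82 in fibroblast. With female cells alone, papain against PBS gave Cd74 0.88 in globose basal, Cyp1a2 0.23 in neutrophil and Il1b 1.70 in fibroblast, and lonidamine against papain gave H2-Ab1 0.18 and H2-Eb1 1.36 in gamma delta T cell and Krt15 0.16 in macrophage. With male cells alone, papain against PBS gave Mmp13 6.20 and Saa3 -3.59 in fibroblast, and lonidamine against papain gave Bpifb4 0.67, Bpifb6 1.35, Fcgbp -0.17 and Gpx6 0.020 in secretory, Coch -0.89, Ear2 -0.51 and Ly6d 0.039 in macrophage, F3 0.77 in dendritic and Gzma 4.12, S100a9 -0.24 and Tff1 2.28 in T cell.

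Shares turned sign, or moved for mature neurons, neutrophils, fibroblasts and ILC2, as follows in log2 ratios. With the stricter cell filter, lonidamine against papain gave neutrophil -0.48. With each library clustered alone, lonidamine against papain gave fibroblast 0.0028, squamous epithelial -1.67 and sustentacular -0.22. With female cells alone, papain against PBS gave mature neuron -1.40 and neutrophil 1.52, and lonidamine against papain gave basal epithelial 0.24, mature neuron -0.72 and neutrophil -0.98. With male cells alone, papain against PBS gave NK cell 0.0097, T cell -0.82 and neutrophil 0.26, and lonidamine against papain gave ILC2 -0.17, dendritic -0.61, fibroblast -0.24, mature neuron 1.49, monocyte -0.49 and neutrophil 0.70.

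Gene list medians turned as follows, or moved for collagen and interferon lists of fibroblast-like cells. With no cell filter, lonidamine against papain gave glycolysis in fibroblast 0.069 and ribosomal protein in neutrophil 0.092. With resolution 0.5, papain against PBS gave interferon in macrophage -0.046. With each library clustered alone, lonidamine against papain gave cell cycle in basal epithelial -2.14, collagens in fibroblast -0.046 and matrix turnover in fibroblast -0.052. With female cells alone, lonidamine against papain gave junction in basal epithelial 0.064 and interferon in pericyte 0.013. With male cells alone, papain against PBS gave interferon in fibroblast 1.52 and NF-kB in fibroblast -0.19, and lonidamine against papain gave cell cycle in basal epithelial -0.70, eosinophil in macrophage -0.75, mucin in secretory -0.88, NF-kB in fibroblast 0.051, ribosomal protein in neutrophil 0.36 and vascular in endothelial -0.42. With cells thinned to 1000 UMIs, papain against PBS gave interferon in secretory -0.24, and lonidamine against papain gave matrix turnover in fibroblast -0.084 and NF-kB in endothelial 0.24. With the mean of per-cell CPM, lonidamine against papain gave NF-kB in endothelial 0.0046 and type 2 in T cell -0.028. With a minimum of 50 CPM, papain against PBS gave interferon in all cells -0.089, and lonidamine against papain gave interferon in basal epithelial 0.10. With the basal epithelial-like cluster led by Ifi202b alone, papain against PBS gave cell cycle in basal epithelial -0.24, and lonidamine against papain gave interferon in basal epithelial 0.13. With the cluster led by Pthlh alone, lonidamine against papain gave cell cycle in basal epithelial -0.10. With the cluster led by Nrcam alone, lonidamine against papain gave cell cycle in basal epithelial -0.0077.

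The second step is the log2 ratio of lonidamine to papain of genes at least 2-fold higher or lower under papain, and these medians turned, or moved in fibroblast-like and basal epithelial-like cells. With no cell filter, genes higher under papain had basal epithelial -0.043, globose basal -0.15 and neutrophil 0.018, and genes lower under papain had dendritic 0.019, endothelial 0.034 and macrophage 0.23. With the stricter cell filter, genes higher under papain had fibroblast 0.030 and globose basal -0.13, and genes lower under papain had macrophage 0.13. With called doublets kept, genes higher under papain had basal epithelial -0.062 and globose basal -0.20, and genes lower under papain had macrophage 0.085. With resolution 0.5, genes higher under papain had globose basal -0.15 and neutrophil 0.043, and genes lower under papain had macrophage 0.081. With resolution 2, genes higher under papain had globose basal -0.13, and genes lower under papain had macrophage 0.019 and sustentacular -0.10. With each library clustered alone, genes lower under papain had sustentacular -0.46. With female cells alone, genes higher under papain had fibroblast 0.057, globose basal -0.14 and neutrophil 0.10, and genes lower under papain had dendritic 0.029, macrophage 0.082 and pericyte 0.12. With male cells alone, genes higher under papain had T cell -0.16, basal epithelial -0.21, endothelial -0.13, fibroblast 0.16, neutrophil 0.14 and pericyte -0.094, and genes lower under papain had endothelial 0.070, macrophage 0.057 and pericyte 0.087. With female cells for the first step and male for the second, genes higher under papain had basal epithelial -0.32, endothelial -0.0013 and fibroblast 0.028, and genes lower under papain had endothelial 0.11, macrophage 0.27 and pericyte 0.0087. With male cells for the first step and female for the second, genes higher under papain had basal epithelial 0.091, and genes lower under papain had dendritic 0.0024 and ionocyte -0.015. With cells thinned to 1000 UMIs, genes lower under papain had ionocyte -0.0093 and sustentacular -0.071. With the mean of per-cell CPM, genes higher under papain had fibroblast 0.16 and macrophage 0.0053, and genes lower under papain had dendritic 0.039 and macrophage 0.052. With median-of-ratios scaling, genes higher under papain had basal epithelial -0.064, and genes lower under papain had basal epithelial -0.033. With 5 counts added, genes higher under papain had T cell -0.0053, fibroblast 0.034, gamma delta T cell -0.15 and globose basal -0.038. With a minimum of 50 CPM, genes higher under papain had basal epithelial -0.037, and genes lower under papain had basal epithelial -0.0089. With no minimum CPM, genes lower under papain had endothelial 0.14 and fibroblast 0.014.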

Other observations

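The look at interferon-stimulated members over all classes, used in this part, was chosen only after the result was seen.

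Of the classes not described so far, ciliated-like cells made up 1.05%, 0.457% and 0.438% of the PBS, papain and lonidamine libraries, and natural killer-like cells 1.17%, 0.752% and 1.03% (papain against PBS 0.0097 in male cells). Tuft or microvillous-like cells (0.375%, 0.971% and 0.657%), plasmacytoid dendritic-like cells (0.150%, 0.371% and 0.388%) and serous gland-like cells (0.171%, 0.410% and 0.371%) were more frequent with papain. Dendritic-like cells made up 2.01%, 2.24% and 2.84% (lonidamine against papain -0.61 in male cells), and B cell-like cells 0.557%, 0.895% and 1.17%.

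Across the compared classes the papain library had glycolysis medians below those of PBS in 14 of 15 and NF-kB medians above in 13 of 15, while lonidamine against papain had a median of glycolysis medians of -0.04. The ribosomal protein list, a technical check, was below PBS in 15 of 15 as well, with a median of medians of -0.38 beside -0.47 for glycolysis. Of these medians 6 and 13 lay under the range of random lists. For lonidamine against papain, nuclear oxidative phosphorylation medians were below 0 in 13 of 15 classes, in both sexes in 10. In 8 they lay under the random range, with a median over classes of -0.11. The ribosomal protein list was below 0 in 13 of 15 too and under the range in 7, with -0.15. Junction medians were above PBS under papain in 12 of 15 classes and below papain under lonidamine in 14 of 15, but in both sexes in 8 only. Free RNA of epithelial classes was not separated from these counts. The same papain library enters both comparisons with opposite sign, and the basal epithelial-like median was 0.06 in female cells.

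Interferon-stimulated genes were lower in the lonidamine library over 140 pairs of member and class, with a median log2 ratio of -0.60 and 112 below 0. Among the 56 pairs at 20% or more of the highest class, the median was -0.51 with 42 below 0. The median of class medians was -0.27 in female and -0.90 in male cells, so the size, which rests on 1 library, differed between the pools of 2 sexes and its cause was not tested.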
